A study of Mus musculus with 4 samples.

How the data were processed

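RNA was measured by sequencing in spermatozoa of adult C57BL/6J mice, an inbred laboratory strain, killed at about 11 weeks of age. Per the labels' protocols, the cauda epididymidis, the storage end of the duct in which sperm mature, was nicked and the spermatozoa were pressed out into a culture medium, and RNA was extracted with Trizol. The labels describe no step that removes other cells. One group had received saline and the other nicotine, the main alkaloid of tobacco, with 2 libraries in each group (saline replicates 1 and 2, nicotine replicates 1 and 2). Dose and route were not given in the sources used here. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

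For each library the authors deposited 1 table of genes with Ensembl identifiers, a short description, a gene length, a read number and an RPKM value (reads normalised to gene length and library total). CASAVA, TopHat and the mouse build mm8 are named, per the submitters' processing notes, without a version or a role. The counting program, the annotation, the strand setting, the treatment of reads that match several genes and any filter on genes were not given in the sources used here. Values of genes with close copies or overlapping neighbours, such as globin, histone, ribosomal protein and glutathione transferase genes, are therefore uncertain. The read column holds reads per gene as deposited by the authors, without normalisation. It was handled like a deposited column of estimated counts, since its last line, which has no gene, holds a fraction, but the values were whole numbers on every gene line and the rounding that precedes the test changed nothing. The deposited RPKM values were recomputed from the read and length columns and the library total, and equalled them apart from rounding of the last digits. RPKM was therefore used only for that check. Each table ended in 1 line without a gene, whose read cell held the factor that turns reads over length into RPKM in that library. It is not a read number, so it has no share of reads and was left out. All tables listed the same 8699 genes. Symbols came from a gene name table for 8688 of them, while 11 kept their identifier. Gene types and GC content came from the GENCODE M21 annotation of GRCm38, which is a later build than mm8, so no coordinates are given. By that annotation 8509 of the genes are protein-coding. The lowest mean count of a listed gene, after median-of-ratios scaling, was 8.83, so genes with lower means were not listed.

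Totals of reads on listed genes were 3999449 and 3856022 in saline replicates 1 and 2, and 3798794 and 5216745 in nicotine replicates 1 and 2. Shares of reads have exact Clopper-Pearson 95% intervals, and a count of 0 was read as up to 3 counts. That floor equals 0.447, 0.473, 2.43 and 0.517 CPM in the same order of libraries. Intervals and floors cover counting error only.

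The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM scaling and group as the only term. Genes were kept by filterByExpr with a minimum count of 10, which left 8375 genes, and 324 were not tested. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05. TMM factors were 1.681, 1.647, 0.325 and 1.113. Levels are given as CPM, which here are reads scaled to the library size after TMM, so their sum differs between libraries. Means are given ± SD over the 2 libraries of a group, and log2 fold changes (nicotine over saline) ± a standard error, which is the size of the log2 fold change divided by the square root of its quasi-likelihood F statistic. Adjusted p-values of genes in the text come from edgeR unless another tool is named.

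26 gene lists were fixed before the data were examined. They cover sperm chromatin packaging, flagellum, acrosome, sperm energy metabolism, meiotic and early germ cells, epididymal epithelium, leukocytes, erythroid cells, connective tissue with vessels, Sertoli and Leydig cells, adipose tissue, nicotinic receptors, xenobiotic metabolism, oxidative stress, apoptosis, heat shock, Wnt signalling, monoamine signalling, insulin and lipid metabolism, DNA methylation and chromatin, imprinted genes, small RNA and translation control, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded messenger RNAs and housekeeping genes. Some genes stand in more than 1 list, such as Ybx2, Clu, Ptgds and Dcn. Many fixed members were not among the deposited genes, so the lists are partial. The deposited genes held 21 of 53 acrosome, 29 of 75 epididymal, 2 of 22 Sertoli and Leydig and 1 of 16 nicotinic receptor members. Other lists were fuller, such as the flagellum list with 40 of 52 and the heat shock list with 31 of 33. Lists with at least 5 tested members (23 of 26) were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2, at the preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Members past the threshold were counted over all genes tested and adjusted over the list alone.

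The rule for named genes was also fixed before the data were examined. It takes the 8 largest rises and the 8 largest falls among called genes with non-overlapping groups and a mean at or above the median of tested genes. It further takes the pair of tested members with the highest mean in each list, the 5 genes with the highest mean of all, Wnt4, the nicotinic receptor subunit with the highest mean, and the protamine and transition protein genes. Predicted genes named Gm with a number were passed over in the first part. The rule named 73 genes, of which 72 were tested. The result of 1 of them is not reported here.

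The test was tried on simulated counts with the real means and library sizes and 200 genes changed by known folds. At the fitted spread it recovered 6% of genes changed 2-fold, 42% at 4-fold, 83.7% at 8-fold and 100% at 16-fold, with 5 false calls, or 0.0616% of the unchanged genes, in a step on 8318 genes in all. At a low spread of 0.02, in a step on 8359 genes, it recovered 32% at 2-fold and 98% at 4-fold, with 7 false calls, or 0.0858% of the unchanged genes. The simulated genes were drawn independently, with 1 spread for all genes and both groups. In the real data the median absolute log2 difference was 0.795 between the nicotine libraries and 0.375 between the saline libraries. The simulated shares of recovered genes and false calls therefore need not hold for these libraries.

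Alternatives fixed in advance were median-of-ratios (RLE) scaling, quantile normalisation, no filter, a stricter filter (mean of at least 5 CPM), DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, and for lists an estimated correlation and fry. Another 5 were added after the data had been seen: scaling by the total of reads, scaling by reads outside Lars2 and Gm42418, scaling to the flagellum list, TMM before the filter, and DESeq2 without a filter. Pseudocount alternatives had been planned for values that are not counts and were not run.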

Results

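Reads per gene were compared between spermatozoa from the cauda epididymidis of mice given saline and of mice given nicotine, with 2 libraries per group. Most reads in every library were counted on a pair of genes, Lars2 (ENSMUSG00000035202), which encodes the mitochondrial leucyl-tRNA synthetase, and Gm42418 (ENSMUSG00000098178), a long noncoding RNA gene. Whether these reads came from transcripts of the pair or from ribosomal RNA of similar sequence was not tested, since counts per gene cannot show it. Together they held 74.9% of reads in saline replicate 1 (exact 95% interval 74.9 to 75.0%), 75.8% in saline replicate 2 (75.8 to 75.9%), 90.6% in nicotine replicate 1 (90.5 to 90.6%) and 77.5% in nicotine replicate 2 (77.4 to 77.5%). None of the 27 other aminoacyl-tRNA synthetase genes had more than 1129 reads in a library. Reads left for all other genes numbered 1002360 and 931578 in the saline libraries, 358477 in nicotine replicate 1 and 1176304 in nicotine replicate 2. The median gene had 44, 40, 8 and 37 reads in the same order, and 2, 13, 317 and 11 genes had 0 reads. Nicotine replicate 1 thus had the fewest reads outside this pair of genes. Across genes, Spearman's rho was 0.858 between the saline libraries and 0.715 between the nicotine libraries. Between groups it was 0.495 and 0.448 for nicotine replicate 1, and 0.688 and 0.700 for nicotine replicate 2, against saline replicates 1 and 2. The median absolute log2 difference over genes was 0.375 between the saline libraries and 0.795 between the nicotine libraries. Against saline replicates 1 and 2 it was 1.09 and 1.17 for nicotine replicate 1, and 0.655 and 0.603 for nicotine replicate 2. By that measure nicotine replicate 2 lay closer to both saline libraries than to nicotine replicate 1. Genes are not independent replicates, so these values only describe the libraries.

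**Figure D1:**
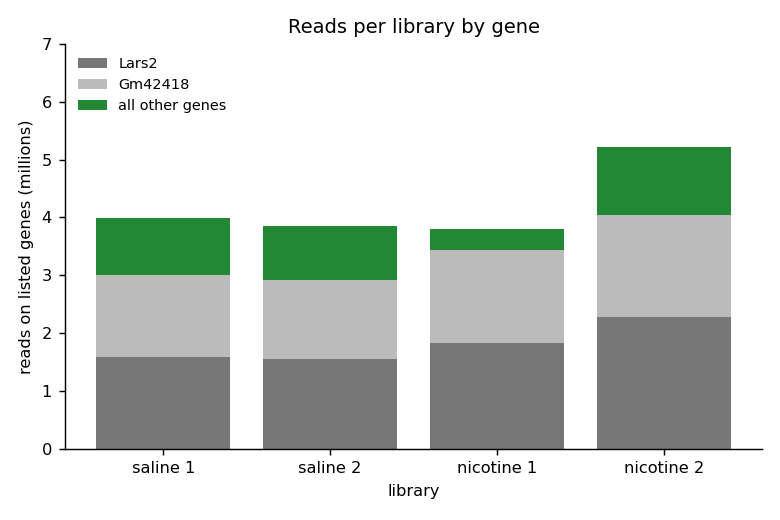
Reads on listed genes in each library (vertical axis, in units of 1e6 reads), stacked as Lars2, Gm42418 and all other genes. The part left for other genes was smallest in nicotine replicate 1, with 358477 reads, and 931578 or more in each of the other libraries.

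The comparison of nicotine with saline asks which sperm RNAs differ after nicotine exposure. As lists and relative to all genes, RNAs of the sperm tail, acrosome, sperm chromatin and sperm energy metabolism were higher in the nicotine libraries by camera at its preset correlation, and those of connective tissue and leukocytes lower. With an estimated correlation none of these 6 lists passed (adjusted p = 0.442 for each), and 2 of 21 connective tissue and 1 of 21 leukocyte members passed on their own. The immediate early gene Fos and the inducible cyclooxygenase Ptgs2 were lower. Smcp, a protein of the sperm mitochondrial capsule, rose by 2.77 ± 0.67 on the log2 scale (adjusted p = 0.0347, edgeR, n = 2 per group), and Fos changed by -4.45 ± 0.67 (adjusted p = 0.0329). Of 8375 tested genes, 693 were higher and 78 lower with nicotine by edgeR's quasi-likelihood test, and 1986 had an unadjusted p under 0.05. The groups did not overlap in any of the 693 and 78 called genes. A call favours genes whose groups lie apart, so this is no further evidence for a difference. Chance alone gives 33.3% of genes such a separation with these numbers of libraries, which holds for genes not picked by a test. The share over all tested genes was not counted.

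The counts and their split depended on single libraries and on the scaling. Without saline replicate 1, 13 genes were higher and 26 lower, and without saline replicate 2 these were 0 and 9 (964 with an unadjusted p under 0.05). Without nicotine replicate 1 they were 935 and 284, and without nicotine replicate 2 they were 1515 and 824. TMM put the median log2 fold change of all genes at -0.14. Scaling by the total of reads, chosen after seeing the data, moved that median to -1.28 and gave 0 genes higher and 9 lower (888 with an unadjusted p under 0.05). Scaling by reads outside Lars2 and Gm42418, chosen likewise, moved it to -0.77 and gave 0 higher and 0 lower by edgeR, with 2523 genes at an unadjusted p under 0.05. Scaling to the flagellum list, also chosen afterwards, holds that list constant by construction. It moved the median to -2.49 and gave 1 gene higher and 6351 lower. Camera therefore serves to compare each list with all other genes. The log2 fold changes and list medians below are as fitted with TMM, unless said to be relative to all genes. The median gene thus lies at -0.14 and not at 0. The oxidative stress list, for example, had a median of -0.10 as fitted and 0.04 relative to all genes.

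Of the 23 lists tested, the flagellum list had the highest median. Of its 34 tested members 25 rose and 0 fell, and 29 rose when adjusted over the list alone. Its median log2 fold change was 2.21, with an adjusted p = 9.98e-18 by camera at the preset correlation and an adjusted p = 0.442 with an estimated correlation. Its median stayed 1.99 to 2.81 above that of all genes over the 17 settings run. Smcp had 547 ± 15.6 CPM with saline and 3724 ± 1444.5 with nicotine. Odf1, a protein of the outer dense fibres that stiffen the tail, went from 450.5 ± 4.12 to 3035 ± 1464.5, a rise of 2.75 ± 0.67 (adjusted p = 0.0348). The list's share of the reads outside Lars2 and Gm42418 was 1.34% and 1.26% in saline replicates 1 and 2, and 4.79% and 4.08% in nicotine replicates 1 and 2. Without saline replicate 1, 2 of 39 members passed the threshold, and without saline replicate 2, 0 of 40. Smcp then had 2.77 (adjusted p = 0.630) and 2.71 (adjusted p = 0.645), and Odf1 2.72 (adjusted p = 0.616) and 2.73 (adjusted p = 0.612), so the size of their rise did not rest on a single saline library.

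Other sperm groups moved the same way. In the chromatin packaging list 7 of 12 members rose and 0 fell, and 12 rose when adjusted over the list alone (median log2 fold change 2.08, camera adjusted p = 6.59e-08, and adjusted p = 0.442 with an estimated correlation). Tnp2, a transition protein that replaces histones before protamines do, rose by 2.05 ± 0.53 (adjusted p = 0.0388, n = 2 per group). The protamine genes did not pass by edgeR over all genes, where Prm1 had 1.80 ± 0.55 (adjusted p = 0.0697) and Prm2 had 1.64 ± 0.58 (adjusted p = 0.111). Both passed when adjusted over the list alone, by DESeq2 (adjusted p = 0.0147 and 0.0126) and by limma-voom (adjusted p = 0.0341 and 0.0452). Tnp1 had 1.80 ± 0.55 (adjusted p = 0.0678 by edgeR and 0.0470 by limma-voom). In the acrosome list 9 of 18 rose and 0 fell, and 13 rose when adjusted over the list alone (median 1.84, camera adjusted p = 7.54e-09, and adjusted p = 0.442 with an estimated correlation). Its most abundant members were Crisp2, a secretory protein of the acrosome, with 140 ± 18.7 CPM in saline and 734 ± 111 in nicotine, and Ace, angiotensin-converting enzyme, with 27.0 ± 6.93 and 102 ± 18.9. Both rose, by 2.39 ± 0.54 (adjusted p = 0.0329) and 1.91 ± 0.49 (adjusted p = 0.0383).

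In the sperm energy list 10 of 22 members rose and 0 fell, and 14 rose when adjusted over the list alone (median 1.77, camera adjusted p = 1.08e-07, and adjusted p = 0.442 with an estimated correlation). Hk1, a hexokinase, rose by 2.84 ± 0.66 (adjusted p = 0.0332), and Pgk2, the phosphoglycerate kinase of male germ cells, by 2.15 ± 0.55 (adjusted p = 0.0392). In the meiotic and early germ cell list 7 of 20 rose and 0 fell, and over the list alone 14 rose and 1 fell (median 1.83, camera adjusted p = 4.11e-06, and adjusted p = 0.442 with an estimated correlation). Syce2, of the synaptonemal complex that joins chromosomes in meiosis, rose by 2.66 ± 0.53 (adjusted p = 0.0329), and Ybx2, a germ cell protein that binds messenger RNA, by 2.07 ± 0.48 (adjusted p = 0.0332). With quantile normalisation 4 members of the chromatin packaging list and 7 of the energy list rose (medians 1.61 and 1.10). By edgeR 0 members of these 4 lists, chromatin packaging to germ cells, passed the threshold with either saline library left out. In the same order of lists 11, 12, 13 and 11 rose without nicotine replicate 1, and 11, 15, 15 and 12 without nicotine replicate 2, while 1 germ cell member fell in the first case and 1 energy member in the second. The log2 fold changes of Tnp2, Crisp2, Ace, Hk1, Pgk2, Syce2 and Ybx2 lay from 1.91 to 2.84 with all libraries, from 2.18 to 2.93 without saline replicate 1 (adjusted p = 0.307 or more) and from 1.65 to 2.70 without saline replicate 2 (adjusted p = 0.384 or more). These log2 fold changes lay from 1.68 to 2.24 without nicotine replicate 1 and from 1.99 to 3.38 without nicotine replicate 2. Hk1 had 2.16 and 3.38 in these cases. With quantile normalisation Tnp2, Ace, Pgk2 and Ybx2 had 1.16, 1.31, 0.89 and 1.55 and did not pass (limma adjusted p = 0.0784, 0.0727, 0.0749 and 0.0542). In the same nicotine libraries the leukocyte and connective tissue lists had medians of -1.32 and -1.58, with 1 and 2 of 21 members lower (adjusted p = 0.442 for both lists with an estimated correlation).

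**Figure D2:**
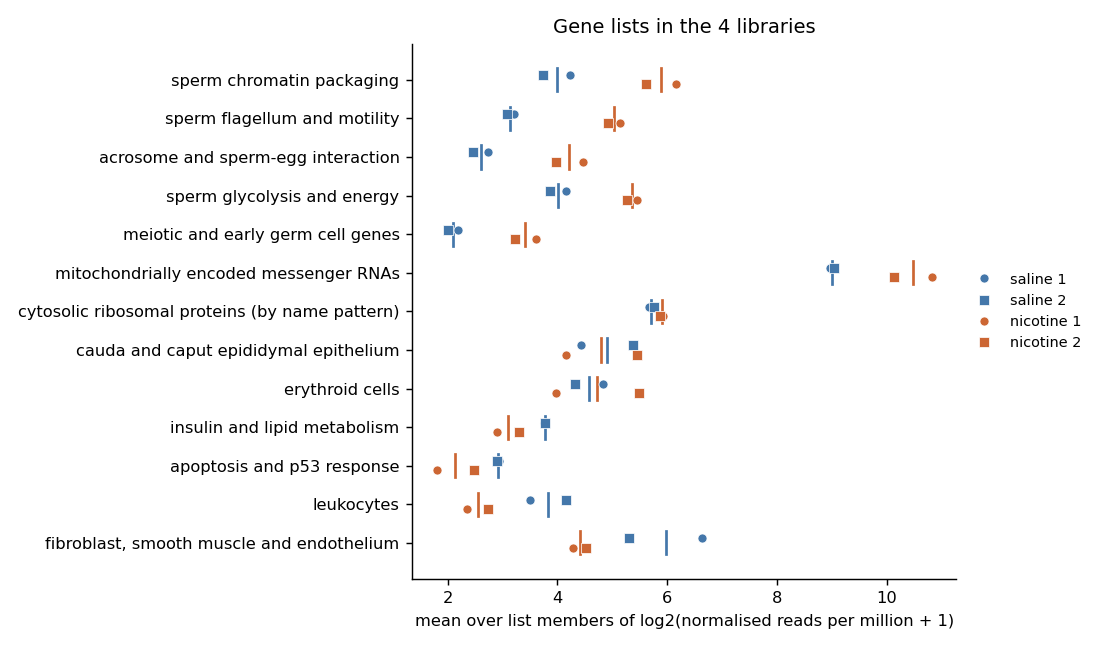
Mean over list members of the log2 of CPM plus 1 (horizontal axis) for 13 gene lists, with a point per library and a line at each group's mean. The flagellum list lay at 3.20 and 3.07 in saline replicates 1 and 2 and at 5.14 and 4.92 in nicotine replicates 1 and 2, while the connective tissue list lay at 6.64 and 5.30 against 4.28 and 4.53.

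Among called genes that met the naming rule, the largest rises were mostly in genes with few reads in saline. The rule asks for a mean CPM at or above the median of tested genes, and a high value in 1 library can lift that mean. Col9a3 had 8 and 3 reads in saline and 46 and 17 in nicotine replicates 1 and 2, or 37.3 and 2.93 CPM in nicotine. Fbp1, a fructose bisphosphatase of gluconeogenesis, had 8 and 3 reads in the saline libraries and 18 and 77 in nicotine replicates 1 and 2, a rise of 4.01 ± 0.65 (adjusted p = 0.0329, n = 2 per group). Satl1, related to the spermidine acetyltransferases, rose by 3.93 ± 0.66 (adjusted p = 0.0329). Wdfy1, an adaptor protein of endosomes, had more reads, with 391 and 306 in saline and 1562 and 1268 in nicotine, and rose by 3.80 ± 0.81 (adjusted p = 0.0329). Its level was 53.2 ± 7.08 CPM in saline and 743 ± 742 CPM in nicotine, where the libraries lay far apart at 1268 and 219 CPM. Col9a3, a collagen chain of cartilage, rose by 4.40 ± 1.10 (adjusted p = 0.0373), Pde6h, a phosphodiesterase subunit of cone cells, by 4.16 ± 0.99, and Myo15, a myosin of inner ear hair cells, by 3.72 ± 0.89 (both adjusted p = 0.0343). The uncharacterised genes 4921509C19Rik and 4732471J01Rik rose by 4.35 ± 0.92 and 3.77 ± 0.90. In 636 of the 693 higher genes nicotine replicate 1 lay above nicotine replicate 2. Of these 8 genes, 6 passed without saline replicate 1, 0 without saline replicate 2 (adjusted p from 0.187 to 0.357), 6 without nicotine replicate 1 and 8 without nicotine replicate 2. The log2 fold change without nicotine replicate 1 was 1.81 for Col9a3 and 1.48 for 4732471J01Rik, neither past the threshold, and 2.06 for Wdfy1, 1.72 for Myo15, 2.56 for 4921509C19Rik and 2.70 for Pde6h. The 8 log2 fold changes spanned 3.84 to 6.12 without saline replicate 1, 3.22 to 3.93 without saline replicate 2 and 4.16 to 5.51 without nicotine replicate 2. By limma-voom 3 of the 8 passed, and Col9a3, Pde6h, Myo15, 4921509C19Rik and 4732471J01Rik did not (adjusted p from 0.0539 to 0.272). With quantile normalisation Col9a3 and 4732471J01Rik did not pass (limma adjusted p = 0.0688 and 0.0547).

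The lower genes included members of the immediate early response. Fosb, a partner of Jun in the AP-1 transcription factor, had 262 and 47 reads in saline and 0 in both nicotine libraries, at least 55.4-fold lower against a floor of 3 counts over the group (adjusted p = 0.0329). Most of its reads lay in saline replicate 1, and the bound was 17.4-fold without that library, 91.4-fold without saline replicate 2, 45.7-fold without nicotine replicate 1 and 9.71-fold without nicotine replicate 2. Fos, another AP-1 subunit, had 30.3 ± 14.5 CPM in saline and 1.18 ± 0.524 in nicotine (n = 2 per group). Ptgs2 went from 21.2 ± 2.08 to 0.862 ± 1.22, a change of -4.02 ± 0.70 (adjusted p = 0.0329). Spp1, the secreted protein osteopontin, had 34 and 439 reads in saline and 2 and 4 in nicotine, a change of -5.30 ± 1.24 (adjusted p = 0.0334). Ctsz, a lysosomal protease, changed by -4.06 ± 0.81 (adjusted p = 0.0329). Of the 78 lower genes, 63 had at most 3 reads in nicotine replicate 1, so their level there was close to the floor. Of the 8 genes with the largest falls, collagens included, 5 passed without saline replicate 1 (adjusted p up to 0.587), 3 without saline replicate 2 (up to 0.467) and 8 with either nicotine library left out. Spp1 had -2.39 without saline replicate 2 and Fos had -3.90 without saline replicate 1 and -5.10 without nicotine replicate 2. Ctsz and Ptgs2 had 0 reads in nicotine replicate 1, so without nicotine replicate 2 they were at least 5.53-fold and 8.71-fold lower against the floor of 3 counts. By limma-voom 5 of the 8 passed, and Spp1, Ctsz and Col5a2 did not (adjusted p from 0.0509 to 0.203). Nor did Spp1 and Col5a2 with quantile normalisation (limma adjusted p = 0.0843 and 0.0549).

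Collagen genes of connective tissue also fell. Col1a1 had 209 ± 183 CPM in saline and 27.6 ± 21.8 in nicotine, a change of -2.98 ± 0.81 (adjusted p = 0.0461, n = 2 per group). Col3a1 went from 328 ± 297 to 41.7 ± 4.12, a change of -2.98 ± 0.72 (adjusted p = 0.0348), and Col5a2 changed by -2.85 ± 0.74 (adjusted p = 0.0400). They had -1.60 (adjusted p = 0.499), -1.52 (adjusted p = 0.553) and -1.66 (adjusted p = 0.587) without saline replicate 1, and -3.69, -3.72 and -3.56 without saline replicate 2, where none of the 3 passed either. Col1a1 had -4.06 without nicotine replicate 1 and -2.19 without nicotine replicate 2, and passed in both cases. In the list of fibroblast, smooth muscle and endothelial genes, 2 of 21 members fell (Col1a1 and Col3a1) and 0 rose, and 9 fell when adjusted over the list alone. By DESeq2 6 fell, by limma-voom 2, and with quantile normalisation 9 fell with a median of -2.28. Its median was -1.58 (camera adjusted p = 4.07e-06, and adjusted p = 0.442 with an estimated correlation). The smooth muscle genes Myh11 and Acta2 had -1.47 ± 0.72 (adjusted p = 0.243) and -1.19 ± 0.71 (adjusted p = 0.346), and passed with quantile normalisation (limma adjusted p = 0.0358 and 0.0424). The saline libraries differed in this list, which held 3.61% and 1.73% of the reads outside Lars2 and Gm42418, against 0.277% and 0.874% in nicotine replicates 1 and 2. Its median was -1.03 without saline replicate 1, where 0 of 21 members passed, and -2.31 without saline replicate 2, where 1 of 23 fell. It was -1.83 without nicotine replicate 1, where 9 fell, and -2.19 without nicotine replicate 2, where 15 fell and 1 rose.

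Among leukocyte markers 1 of 21 fell and 0 rose, and 6 fell when adjusted over the list alone. With DESeq2 3 fell, and likewise 3 with quantile normalisation. The median was -1.32 (camera adjusted p = 3.78e-05, and adjusted p = 0.442 with an estimated correlation). The member that fell was Cd14, a receptor of macrophages for bacterial lipopolysaccharide, with 92 reads in saline and 3 in nicotine, a ratio of 16.5 (95% counting interval 5.47 to 81.5). It was named after its values were seen. Its adjusted p was 0.105 without saline replicate 1 and 0.313 without saline replicate 2, and without nicotine replicate 2 it was at least 2.89-fold lower against a floor of 3 counts. Neither of the most abundant markers passed by edgeR. Lyz2, lysozyme of myeloid cells, had -1.58 ± 0.55 (adjusted p = 0.107, and limma adjusted p = 0.0381 with quantile normalisation), while Cd52, also abundant in the epididymal epithelium, had 0.11 ± 0.68 (adjusted p = 0.943). Members past the threshold numbered 3 without saline replicate 1, 0 without saline replicate 2, 8 without nicotine replicate 1 and 8 without nicotine replicate 2.

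**Figure D3:**
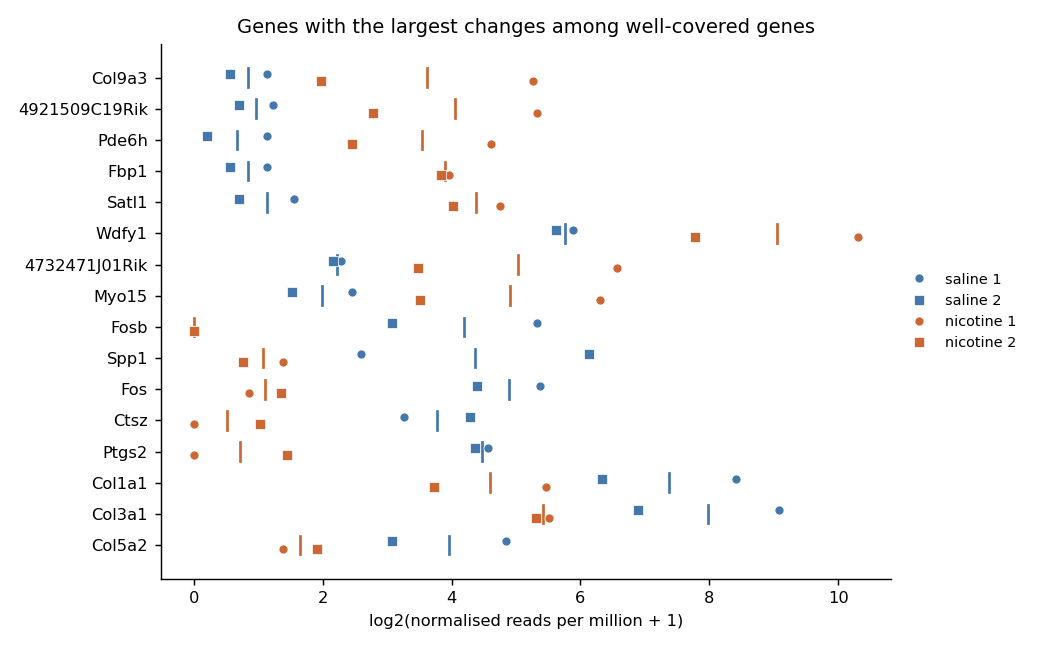
The log2 of CPM plus 1 (horizontal axis) of the 16 genes named for the largest changes, with a point per library and a line at each group's mean. Their mean CPM was at or above the median of tested genes, which can rest on 1 library. Fosb had 0 reads in both nicotine libraries, and Wdfy1 had 1268 and 219 CPM in nicotine replicates 1 and 2.

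Mitochondrially encoded messenger RNAs were higher relative to all genes as a list only by camera at its preset correlation. None of the 13 members passed by edgeR over all genes, where 9 had an unadjusted p under 0.05, and 7 rose when adjusted over the list alone. DESeq2 called 10 of them higher and limma-voom 6. The median was 1.56 (camera adjusted p = 4.29e-06, and adjusted p = 0.442 with an estimated correlation), and it was 0.36 with quantile normalisation. The cytochrome oxidase genes mt-Co1 and mt-Co3 had 1.04 ± 0.84 (adjusted p = 0.495) and 1.16 ± 0.68 (adjusted p = 0.332). The list held 11.8% and 11.9% of the reads outside Lars2 and Gm42418 in saline and 19.3% and 14.9% in nicotine replicates 1 and 2. Without nicotine replicate 1, 9 members rose, without nicotine replicate 2, 13, and with either saline library left out, 0. Lars2 and Gm42418 themselves had 1.97 ± 1.67 (adjusted p = 0.518) and 1.91 ± 1.63 (adjusted p = 0.522) by edgeR, while DESeq2 called both higher (adjusted p = 0.0175 and 0.0262). As a share of all reads, Gm42418 held 35.27% and 35.79% in saline and 42.31% and 33.88% in nicotine replicates 1 and 2. Its share in nicotine replicate 2 thus lay below both saline libraries. Lars2 held 39.67% and 40.05% against 48.25% and 43.57%. Gm43305, another of the 5 most abundant genes, had 1.25 ± 0.93 (adjusted p = 0.455).

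Lists of apoptosis and of insulin and lipid metabolism were lower relative to all genes by camera at its preset correlation, without a member past the threshold. In the apoptosis list 0 of 16 members passed by edgeR, also over the list alone, with 2 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. The median was -0.86 (camera adjusted p = 0.0213, and adjusted p = 0.442 with an estimated correlation). Mcl1, which protects cells from apoptosis, had -1.41 ± 0.49 (adjusted p = 0.101), and Xiap, a caspase inhibitor, had -0.32 ± 0.60 (adjusted p = 0.798). The list's adjusted p was 0.0518 without nicotine replicate 1, and without nicotine replicate 2 its median was -1.62 with 5 members lower. With the stricter filter its median was -0.46 (adjusted p = 0.146), and with scaling to the flagellum list its adjusted p was 0.112. In the insulin and lipid list 0 of 27 passed by edgeR, also over the list alone, with 5 at an unadjusted p under 0.05. DESeq2 called 1 higher and 1 lower, and limma-voom 1 lower. The median was -0.64 (camera adjusted p = 0.00334, and adjusted p = 0.442 with an estimated correlation). Fasn and Scd2, enzymes of fatty acid synthesis and desaturation, had -0.89 ± 0.48 (adjusted p = 0.295) and -0.70 ± 0.58 (adjusted p = 0.509). Without nicotine replicate 2, 1 of its members was higher and 10 were lower.

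Markers of the epididymal epithelium did not separate the groups. None of 27 passed by edgeR, over all genes or over the list alone, with 1 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. The median was 0.10 while the mean was -0.02 and camera's direction was down (adjusted p = 0.684). The list's share of the reads outside Lars2 and Gm42418 was 1.30% and 3.66% in saline and 0.770% and 3.03% in nicotine, so it differed more within each group than between them. Crisp1 and Ces5a, secreted by the epithelium, had 0.55 ± 0.73 (adjusted p = 0.698) and -0.01 ± 0.63 (adjusted p = 0.994). Without nicotine replicate 1 the list passed camera upward with a median of 0.58, and without nicotine replicate 2 it passed downward with -0.79 and 5 members lower. Without saline replicate 1 it passed downward with -0.40, and without saline replicate 2 its median was 0.80 and it did not pass. Among erythroid genes 1 of 7 rose, Car2, a carbonic anhydrase also made in other cells, and 1 over the list alone (median 0.29, camera adjusted p = 0.684). The globin genes Hbb-bs and Hba-a1 had 0.14 ± 0.68 (adjusted p = 0.929) and 0.10 ± 0.61 (adjusted p = 0.944). The erythroid list passed upward with a median of 0.88 without nicotine replicate 1, its median was -1.06 with 1 member higher and 1 lower without nicotine replicate 2, and with either saline library left out 0 of its members passed. Of the Sertoli and Leydig cell list 2 members were tested. By edgeR 0 passed, also over the list alone and at an unadjusted p under 0.05, and 0 by DESeq2 or limma-voom (median -0.35). Clu had -0.80 ± 0.81 (adjusted p = 0.596) and Ptgds 0.10 ± 0.60 (adjusted p = 0.940), and 1 of them was lower without nicotine replicate 2. In the adipose list 1 of 6 rose, Lipe, hormone-sensitive lipase, by 2.02 ± 0.48 (adjusted p = 0.0337), while over the list alone 1 rose and 3 fell (median -1.05, camera adjusted p = 0.533). Scd1 had -0.27 ± 0.48 (adjusted p = 0.784). By DESeq2 1 adipose member rose and 2 fell. By edgeR 0 rose and 2 fell without saline replicate 1, 2 rose and 2 fell without nicotine replicate 1, and 1 rose and 1 fell without nicotine replicate 2. Lipe had an adjusted p = 0.383 without saline replicate 1 and 0.508 without saline replicate 2, and a limma adjusted p = 0.0572 with quantile normalisation.

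Of the nicotinic acetylcholine receptor subunits 1 was listed, Chrna2, and it was not tested, with 25 and 5 reads in saline and 4 and 12 in nicotine. In the xenobiotic metabolism list 1 of 16 rose, the glutathione transferase Gstm5 (2.47 ± 0.62, adjusted p = 0.0374), and 1 fell, Tiparp, a target of the aryl hydrocarbon receptor (-2.32 ± 0.63, adjusted p = 0.0456). The call of Tiparp ended under DESeq2, limma-voom and quantile normalisation, with 0 members lower in each, and DESeq2 called 2 higher. Over the list alone 2 rose and 1 fell (median -0.91, camera adjusted p = 0.134). Gstm1 had -0.18 ± 0.46 (adjusted p = 0.853). Gstm5 had an adjusted p = 0.549 without saline replicate 1 and 0.590 without saline replicate 2, and 0 members of the list passed in either case. Without nicotine replicate 2, 2 members were higher and 2 lower. Of the monoamine list 4 members were tested, 0 passed by edgeR (1 at an unadjusted p under 0.05, 1 higher by DESeq2, 0 by limma-voom) and 1 rose over the list alone (median -0.48, mean 0.34). Tph2, a tryptophan hydroxylase, had 3.20 ± 0.98 (adjusted p = 0.0680, and 0.00561 by DESeq2). It had few reads, 7 and 10 in saline and 31 and 15 in nicotine replicates 1 and 2. These equal 1.04 and 1.58 CPM against 25.2 and 2.59, so the size of this change rests mainly on nicotine replicate 1.

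Wnt4 had -0.36 ± 0.55 (adjusted p = 0.749), with 38 and 47 reads in saline and 5 and 33 in nicotine. In the Wnt list 1 of 25 rose, Wnt3, by 2.65 ± 0.49 (adjusted p = 0.0329), and 1 over the list alone (median -0.30, camera adjusted p = 0.153). The abundant members Ctnnb1 and Csnk1a1 had -0.30 ± 0.45 (adjusted p = 0.744) and -0.74 ± 0.55 (adjusted p = 0.452). In the oxidative stress list 0 of 33 passed by edgeR, also over the list alone, with 7 at an unadjusted p under 0.05, 0 by DESeq2 and 1 higher by limma-voom (median -0.10, camera adjusted p = 0.586). Gpx4, which reduces lipid peroxides in sperm, had 0.92 ± 0.47 (adjusted p = 0.264), and Gpx3 had -0.13 ± 0.61 (adjusted p = 0.924). In this list 4 members were higher and 2 lower without nicotine replicate 1 (median 0.25), and 2 were higher and 4 lower without nicotine replicate 2 (median -0.79), while camera did not pass in either case. In the heat shock list 4 of 30 rose (Dnajb3, Dnajb4, Hspa4l and Hspb9), and 4 over the list alone. Its median was 0.04 while camera's direction was down (adjusted p = 0.954). The small heat shock protein gene Hspb9 rose by 2.48 ± 0.58 (adjusted p = 0.0336), and Hsp90ab1 had -0.30 ± 0.47 (adjusted p = 0.754). Hspb9 had 1.75 without nicotine replicate 1 and 3.06 without nicotine replicate 2. The adjusted p of Hspb9 was 0.347 without saline replicate 1 and 0.473 without saline replicate 2, and 0 members of the Wnt and heat shock lists passed in either case. Without nicotine replicate 2, 2 members of the Wnt list were higher and 2 lower, and of the heat shock list 5 were higher and 2 lower, with a median of -0.54.

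Of regulators of DNA methylation and chromatin 0 of 36 passed by edgeR, also over the list alone, with 5 at an unadjusted p under 0.05, 0 by DESeq2 and 1 higher by limma-voom (median -0.30, camera adjusted p = 0.615). Hdac6, a deacetylase, had -0.51 ± 0.48 (adjusted p = 0.563), and Ehmt2, a histone methyltransferase, had 1.27 ± 0.46 (adjusted p = 0.119). In this list 1 member was higher and 1 lower without nicotine replicate 1, and 7 were higher and 2 lower without nicotine replicate 2, where camera's direction was up (adjusted p = 0.960). Of imprinted genes 0 of 14 passed by edgeR, also over the list alone, with 4 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom (median -0.51, camera adjusted p = 0.0652), with Dcn at -1.78 ± 0.68 (adjusted p = 0.136) and Igf2r at -1.40 ± 0.55 (adjusted p = 0.146). The imprinted list passed camera downward without saline replicate 2 (adjusted p = 0.0177) and with the stricter filter (median -1.17, adjusted p = 0.0257), and without nicotine replicate 2 its median was -1.60 with 3 members lower (camera adjusted p = 0.0699). In small RNA and translation control 1 of 22 rose, Ybx2, and 1 over the list alone (median 0.46, camera adjusted p = 0.153), with Eif4g1 at 0.93 ± 0.54 (adjusted p = 0.331) and Pabpc1 at 0.46 ± 0.47 (adjusted p = 0.604). Of that list 4 members rose without nicotine replicate 1, 4 rose and 2 fell without nicotine replicate 2, and 0 passed with either saline library left out.

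Among cytosolic ribosomal protein genes 1 of 77 rose, Rpl39l, a form made in the testis, and 0 over the list alone (median 0.10, camera adjusted p = 0.153). Without nicotine replicate 2, 11 of them rose, and with either saline library left out 0. With quantile normalisation their median was -0.55 and the list passed downward. Rpl41 had 0.75 ± 0.48 (adjusted p = 0.380) and Rplp0 had -0.15 ± 0.49 (adjusted p = 0.893). In nuclear-encoded oxidative phosphorylation 0 of 72 passed by edgeR, also over the list alone, with 2 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom (median -0.19, camera adjusted p = 0.150), with Atp5b at -0.64 ± 0.53 (adjusted p = 0.509) and Atp5a1 at -0.86 ± 0.55 (adjusted p = 0.385). Of the housekeeping genes 0 of 15 passed by edgeR, also over the list alone and at an unadjusted p under 0.05, and 0 by DESeq2 or limma-voom (median -0.32, camera adjusted p = 0.143), with Actb at -0.91 ± 0.50 (adjusted p = 0.304, and limma adjusted p = 0.0352 with quantile normalisation) and B2m at 0.10 ± 0.63 (adjusted p = 0.940). Both lists passed downward without nicotine replicate 2, with an adjusted p = 0.0213 (1 member higher and 6 lower) and 0.0477 (3 lower). The housekeeping list also passed downward with quantile normalisation (median -0.97, adjusted p = 0.00185, 1 member lower).

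Of the 23 lists tested, 6 passed upward and 4 downward at the preset correlation. With an estimated correlation 0 passed, with a lowest adjusted p = 0.442, when the lists were compared with all other genes. Among the lists that passed at the preset correlation of 0.01, the estimated correlation ranged from 0.0411 (apoptosis) to 0.873 (mitochondrially encoded messenger RNAs). It was 0.468 for chromatin packaging and 0.0793 for the flagellum list. The fry test asks instead whether a list's genes moved, on balance, from no change, and 0 passed it, with a lowest adjusted p = 0.0667.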

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

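Scaling by the total of reads, by reads outside Lars2 and Gm42418 and to the flagellum list, TMM before the filter and DESeq2 without a filter were tests chosen after the result was seen; the others were planned. RLE scaling, both filters, DESeq2, TMM before the filter and DESeq2 without a filter kept the numbers of higher and lower genes within 1.5 times of 693 and 78, as did quantile normalisation, which shared 545 of the calls; limma-voom gave 46 lower genes. No gene called both with TMM and under an alternative changed sign. The replicate number as a block gave 1357 genes (1078 higher, 279 lower). The labels do not pair the samples, and the deviations of same-numbered libraries correlated at 0.173 over genes with only 2 pairs, so the numbers were not taken as a pairing. Scaling by the total of reads gave 9 genes (0 higher, 9 lower), by reads outside Lars2 and Gm42418 0 (0 and 0), and to the flagellum list 6352 (1 higher, 6351 lower); by construction each shifts all genes of a library alike. With each library left out in turn, called genes ranged from 9 to 2339, higher genes from 0 to 1515 and lower genes from 9 to 824; without saline replicate 1 there were 39, of which 25 were among the 771, and without saline replicate 2 there were 9, of which 4 were. Such a fit leaves 1 library in a group, assumed to vary like the other group, so its spread comes from the pair that is left, and the nicotine pair lay further apart (rho 0.715) than the saline pair (0.858).

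With an estimated correlation 0 lists passed in place of 10, and with fry 0. Camera at the preset correlation called the flagellum, chromatin packaging, acrosome, energy, meiotic, leukocyte, connective tissue and insulin lists in the same direction under all 14 settings in which it was run, the mitochondrial list in 13 and the apoptosis list in 11. DESeq2 and limma-voom change the test of genes and not the values that camera reads, so they gave no list test of their own. Camera called the ribosomal protein list downward with quantile normalisation, where its median was -0.55, or -0.39 relative to all genes, and with scaling to the flagellum list, where its median of -2.32 lay 0.17 above that of all genes, so that median and test differ in sign; the cause was not tested. With the block the imprinted list also passed downward (adjusted p = 0.0396), as did the housekeeping list under scaling to the flagellum list (adjusted p = 0.0363). The epididymal list ranged from -0.79 to 0.80 and Hbb-bs from -1.38 to 0.88 with 1 library left out. Scaling to the flagellum list lowers every gene by construction. It turned Crisp2 to -0.083, Ace to -0.55, Pgk2 to -0.38, Ybx2 to -0.31, Tnp2 to -0.45, Lipe to -0.42, Gstm5 to -0.11 and Hspb9 to -0.093, none past the threshold. It turned Cd52 to -2.16, Hba-a1 to -2.14, Ptgds to -2.23, Gpx4 to -1.50, Eif4g1 to -1.65, Pabpc1 to -1.93, Rpl41 to -1.71, mt-Co1 to -1.55, mt-Co3 to -1.39 and B2m to -2.15, all past it.

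Of named gene values under settings that keep all libraries, apart from the 3 added scalings that shift all genes of a library alike, 580 kept direction and side of the threshold, 19 lost and 25 gained a call and 0 reversed, while 21 changed sign without a call on either side. Under those 3 scalings the numbers were 80, 64, 24, 18 and 30, with all 18 reversals under scaling to the flagellum list. With a library left out they were 191, 44, 30, 1 and 22. For lists under camera they were 128, 1, 3, 1 and 5, under the 3 scalings 62, 2, 1, 1 and 3, and with a library left out 77, 1, 6, 1 and 7. The 50 most abundant genes held up to 94.8% of a library. Depth limits how low a level can be measured, as 3 counts equal 2.43 CPM in nicotine replicate 1 and 0.447 in saline replicate 1.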

Other observations

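The tests of scaling, of the share of other cells and of immediate early genes, the tests of gene families and the count of sample splits were chosen only after the result was seen; those of gene length with GC content and of thinned reads were written before. Further calls were counted in families grouped by the start or end of gene symbols and on the X chromosome (28 tests by Fisher's exact test, Benjamini-Hochberg adjusted). This test takes genes as independent, which genes measured in the same libraries are not. Its p-values therefore do not measure the spread between libraries. Of 47 genes of axonemal dyneins and cilia, which build and move the tail, 23 were higher with nicotine (adjusted p = 3.03e-12). So were 13 of 23 Spata and Spag genes (adjusted p = 3.75e-08) and 9 of 18 Tex, Tsga and Tssk genes (adjusted p = 2.97e-05). Of 161 genes named only after RIKEN clones 34.8% were higher, against 7.76% of the rest (adjusted p = 2.19e-20), as were 15 of 54 Ccdc genes of coiled-coil proteins (adjusted p = 0.000114) and 23 of 162 genes of the ubiquitin system (adjusted p = 0.0320), which is not particular to sperm. X-linked genes were called higher less often, 8 of 224 or 3.57% (adjusted p = 0.0261), and of 27 collagen genes 4 were lower (adjusted p = 0.000485) and 2 higher, 7.41% against 8.28% of the rest. The first 3 families had 0 members higher with either saline library left out. Without nicotine replicate 1 they had 27, 16 and 12. Higher genes numbered at most 1 in the RIKEN, Ccdc, ubiquitin and X-linked groups with either saline library left out. Without nicotine replicate 1 the unadjusted p of Fisher's exact test was 1.49e-21, 8.65e-09, 0.0562 and 0.0174 in the same order, and without nicotine replicate 2 it was 7.22e-20, 5.33e-05, 0.0176 and 1.01e-06. Lower collagen genes numbered 0 without saline replicate 1, 1 without saline replicate 2 and 12 with either nicotine library left out.

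A few other lower genes were named after their values were seen. The elastase Mmp12 had 171 reads in saline and 1 in nicotine, a ratio of 92 (95% counting interval 16.3 to 3660), and the cytokine gene Tnf had 144 and 1, a ratio of 77.5 (13.7 to 3080). Ctsb, a lysosomal protease, went from 132 ± 94.9 to 27.2 ± 7.43 CPM (-2.27 ± 0.62, edgeR adjusted p = 0.0461, n = 2 per group). The nuclear noncoding RNA Neat1 went from 101 ± 9.30 to 19.4 ± 3.31 CPM (-2.36 ± 0.49, edgeR adjusted p = 0.0329, n = 2 per group). In both, the 2 nicotine libraries lay below the 2 saline libraries. The edgeR adjusted p was 0.159 for Ctsb and 0.263 for Neat1 without saline replicate 1. It was 0.350 for Mmp12, 0.381 for Tnf, 0.642 for Ctsb and 0.315 for Neat1 without saline replicate 2, where the ratios of Mmp12 and Tnf were 20.9 (95% counting interval 3.35 to 868) and 17.8 (2.79 to 744) and Ctsb had -1.27. Mmp12 was at least 5.38-fold lower against a floor of 3 counts without nicotine replicate 2, where Tnf had a ratio of 13.6 (2.40 to 540), and Tnf was at least 21.3-fold lower without nicotine replicate 1. Without saline replicate 1 the ratios of Mmp12 and Tnf were 167 (29.6 to 6650) and 141 (24.8 to 5600).

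Camera at its preset correlation called sperm lists higher and connective tissue and leukocyte lists lower in the nicotine libraries, while with an estimated correlation none passed (adjusted p = 0.442 for each). The scaling is not the cause of the contrast between the flagellum and connective tissue lists: the log2 ratio of their summed reads within a library, which no scaling moves, was -1.43 and -0.45 in saline and 4.11 and 2.22 in nicotine replicates 1 and 2, a gap of 2.67 against at most 1.89 within a group, and that of their median members had a gap of 3.08 against at most 1.35. A trend on gene length or GC content is excluded as the whole cause, since its removal left the flagellum median at 2.24 (2.21 before), although 15 members passed in place of 25. A smaller share of RNA from cells other than spermatozoa remains a candidate explanation that cannot be told apart from a change in sperm RNA. The form tested takes an unchanged mix of those cells. That mix already differed between saline replicates 1 and 2. There the connective tissue list lay 3.44 and 2.23 above the flagellum list, and the epididymal list 1.22 and 2.30 above it (log2 of CPM plus 1). All 4 lists of other cells fell relative to the flagellum list on the scale of log2 of CPM plus 1 (± a standard error over libraries), by -1.99 ± 0.92 (epididymal), -3.17 ± 0.50 (leukocytes), -1.74 ± 0.88 (erythroid) and -3.46 ± 0.65 (connective tissue). The flagellum list had the highest median of the 23 lists tested, so any other list tends to fall against it. These falls alone therefore do not bear on this explanation. Relative to all genes, the medians were 0.24 (epididymal), 0.43 (erythroid), -1.18 (leukocytes) and -1.44 (connective tissue), so the epididymal and erythroid lists did not fall. Of the 6 pairs of these lists, 2 moved apart by more than the first criterion of 2 standard errors. These were the leukocyte and epididymal lists, by 2.53, and the erythroid and connective tissue lists, by 2.27. Each standard error rests on 2 libraries per group, so passing that bound is only weak evidence against an unchanged mix. Under a criterion set after that result was seen, the largest gap between groups was 0.67 of the largest difference within a group. No verdict is therefore drawn, and nicotine itself stays open.

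Nicotine replicate 1 had 317 genes at 0, and fewer reads outside Lars2 and Gm42418 are excluded as the whole cause. Thinned to the same number of such reads, the other libraries had at most 104.5 genes at 0 on average over 20 draws. What else sets that library apart was not tested.

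Immediate early genes were lower with nicotine in a list written after the data were seen. Of its 27 members 12 fell and 0 rose, with a median of -2.34. The list holds Fos, Fosb and Ptgs2, which are among the largest falls above, so its test is no further evidence. Its unadjusted camera p was 2.72e-11 at the preset correlation and 0.0538 with an estimated one. The same unadjusted values were 4.34e-19 and 0.0322 for the flagellum list. Called members numbered 3 with either saline library left out, 17 without nicotine replicate 1 and 15 without nicotine replicate 2. Whether less RNA from connective tissue alone accounts for the lower immediate early genes is left open. The saline libraries differed by 0.37 ± 0.16 (log2) in immediate early genes and by 1.34 ± 0.23 in connective tissue genes. Here ± is a standard error over the genes of a list, with 1 library on each side. It does not measure the spread between libraries. The values fell short of the bound set for exclusion, but the differences were also not alike, so the test cannot decide. A response of living cells during collection was not tested.

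The 4 libraries can be split into 2 and 2 in 3 ways. The real split gave 771 genes, the highest of the others gave 0, and 1 split gave as many as the real one, itself; so few splits cannot give a share under 0.05.

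The deposited tables list 975 genes in order of identifier and then 7724 more, again in order. Of the tested genes, 78.4% of the first block were called (733 of 935), and 0.511% of the second (38 of 7440). With DESeq2 without a filter the numbers were 938 of 975 and 47 of 7724. The labels and headers used here do not say what the order stands for.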
